A study of Homo sapiens with 7 samples.

How the data were processed

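RNA from 7 samples of H1 human embryonic stem cells was measured by paired-end sequencing of poly(A) RNA selected with oligo(dT) beads. The labels give wild-type cells in E8 medium, either untreated for 48 h (n = 2) or with XMD892 at 1 µM for 12 h (n = 1), 24 h (n = 2) or 48 h (n = 2). Cells were collected in RNAiso Plus and libraries were read on an Illumina NextSeq instrument.

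The authors name Trimmomatic 0.36, STAR, featureCounts 1.5.3 and DESeq2 1.26.0 and the hg38 genome, without saying which step each served; the gene annotation, the strand setting and any filter are not given. The deposited values are a signal per gene symbol, gene read counts that the authors divided by 1 factor per library. Each value divided by its library's smallest step was within 0.1 of a whole number in 100% of the values, so whole reads could be recovered. The file lists 19775 genes, the lowest with 6 reads over the 7 libraries, and the lowest row mean was 0.81, so rows of genes with very few reads are not analysed here. Its 2 further columns are named as XMD at 12 h, but they match no sample and were used in no step.

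Total reads per library were computed from the recovered reads and lay between 18528689 and 24148186; they cover the listed genes only. Over all genes compared, the squared difference between replicates was 33.0 times that of counting error in E8, 9.79 times at 24 h and 9.76 times at 48 h. Gene symbols were matched to GENCODE 29 on GRCh38, which gave coordinates for 97.7% of them (19319), and transcript GC content for 98% of the tested genes. Some symbols are older names, for example CTGF, and are printed as the file has them.

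Genes with a mean of 10 or more over the 7 libraries (16351) were tested. Values were taken to log2 after adding a pseudocount of 1, and limma 3.58.1 (R 4.3.3) fitted 1 mean per group to all 7 libraries with a trended prior variance, leaving 3 residual degrees of freedom and a prior of 18.4. Each time was compared with E8, and 48 h with 24 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. At 12 h the single library is assumed to vary like the other groups, as is the lone library of a group when its other replicate is left out. In data simulated at these levels, 74.6% of genes changed 2-fold and 26.9% of genes changed 1.5-fold were called at 48 h, with 10 calls among 16151 unchanged genes. The shares at 24 h were 65.7% and 28.4% and at 12 h 58.2% and 4.5%. These simulations drew genes independently, changed few of them and left out the difference between the E8 libraries along GC content. They therefore do not give the rate of false calls or the power in the data.

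Before the data were examined, 46 gene lists with 717 entries were fixed, along with the comparisons, the alternatives and the rule for named genes. Some genes stand in more than 1 list. Lists with at least 5 tested members (43) were tested against all other genes with camera at a preset correlation of 0.01, and again with the correlation estimated; fry tested whether each list moved on balance one way. All camera and fry p-values printed as adjusted are Benjamini-Hochberg adjusted over the 43 lists. Members were also called with the adjustment over the list alone. Tested on 41 simulated lists, camera with the preset correlation called the list that was shifted and no random list. The simulated genes were drawn independently, so this does not show how often camera calls lists of correlated genes. In the data the estimated correlation lay between -0.148 (trophoblast and amnion) and 0.705 (glycolysis). It was -0.014 for the ligand list, -0.037 for NODAL and TGFβ targets and -0.094 for metallothioneins, all below the preset 0.01. For these lists the higher p with an estimated correlation therefore does not come from correlation among their genes.

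The genes named are those of a fixed set (MAPK7, MAP2K5 and known pluripotency, lineage and signalling genes), the 10 largest changes each way at 24 h and at 48 h and the 5 largest each way at 12 h and between 24 h and 48 h, among called genes with non-overlapping libraries and a mean of 100 or more in a group, and up to 4 called members of each list. TBXT, EOMES, GATA3 and KLF2 had means under 10, and PAX6 and CDX2 were not analysed here.

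Alternatives were pseudocounts of 0.5 and 5, no filter, a filter at a mean of 50, rescaling by TMM factors (edgeR 4.0.16), to the same total or by quantiles, edgeR and DESeq2 1.42.0 on the recovered reads, robust variance moderation, a fit of only the groups compared, replicate numbers as a block, and leaving out each replicate in turn. Removing each library's trend along GC content (loess, span 0.3), also without either E8 library, the test of lists between 24 h and 48 h, and a test of the later genes with a different 48 h library in each comparison were added after seeing the data. No group had 3 or more libraries, so other splits of the samples were not counted. Replicate numbers showed no pairing of libraries across groups.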

Results

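Poly(A) RNA was sequenced from 7 samples of H1, an established line of human embryonic stem cells grown in E8, a defined medium that contains FGF2 and TGFβ. XMD892, a kinase inhibitor that the study's title links to ERK5, was added at 1 µM for 12, 24 or 48 h. The groups held 2 E8 samples harvested at 48 h, 1 sample at 12 h of XMD892, 2 at 24 h and 2 at 48 h. The listed genes carried 22310348 and 24148186 reads in the E8 libraries, 18528689 at 12 h, 18887150 and 21551210 at 24 h and 18759059 and 19818798 at 48 h. Of 19775 genes, 16351 had a mean normalised read count of 10 or more and were tested. Values are normalised read counts, given as mean ± SD of 2 libraries, and the 12 h group has no replicate. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples. Wherever a gene is named as higher or lower by the test, every library of the first group lay on the same side of every library of the other.

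The first principal component carried 41.2% of the variance and set E8, at 56.8 and 38.5, apart from the XMD892 libraries, which lay between -27.0 and -14.0. The second carried 20.6% and ordered the treated libraries by time, with 38.6 at 12 h, 7.2 and 9.3 at 24 h and -30.9 and -26.0 at 48 h. The E8 libraries differed from each other along GC content, with a Spearman correlation across 12516 genes, which are not independent replicates, of -0.75 between the log2 difference of the pair and transcript GC content. The same correlation was -0.01 for the 24 h pair and 0.29 for the 48 h pair. The SD of the log2 difference between replicates was 0.466 in E8, 0.395 at 24 h and 0.412 at 48 h.

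The comparison of 48 h of XMD892 with E8 addressed what the inhibitor did to the cells' own growth factor signals, the autocrine balance that the title names. NODAL, a TGFβ-family ligand, fell from 690 ± 130 (SD, n = 2) in E8 to 80.5 ± 3.93 at 48 h (n = 2), 8.41-fold lower. GDF3, of the same family, fell from 1009 ± 65.1 to 146 ± 49.7, and FGF8, a fibroblast growth factor, from 245 ± 4.73 to 17.2 ± 3.23, 13.6-fold lower. TBX10, a T-box transcription factor, rose from 46.4 ± 13.8 to 512 ± 81.2, a log2 fold change of 3.46, and TXNIP, which binds thioredoxin, rose from 232 ± 28.8 to 1462 ± 83.6. MAPK7, the gene of ERK5, stood at 719 ± 11.6 in E8 and 718 ± 65.0 at 48 h, with a log2 fold change of -0.01 and a limma adjusted p of 0.99. MAP2K5, the kinase that activates ERK5, stood at 342 ± 15.5 and 317 ± 3.71 (log2 fold change -0.11, limma adjusted p = 0.76).

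At 48 h, 1884 genes passed limma at a Benjamini-Hochberg adjusted p under 0.05, of which 830 were higher than in E8 and 1054 lower. The count was 4038 without E8 replicate 2, 751 without 48 h replicate 1 and 823 without 48 h replicate 2, and it was 1600 without E8 replicate 1. Without E8 replicate 2 the balance turned, to 2390 higher and 1648 lower, and without 48 h replicate 1 it was 202 and 549. With each library's trend along GC content removed, an alternative chosen after seeing the data, 3078 genes passed and 96.9% of the 1884 kept their call and direction.

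The list of autocrine FGF, NODAL and WNT ligands also holds the NODAL antagonists LEFTY1 and LEFTY2, the co-receptor TDGF1 and other growth factors such as BMP4. All are counted here as ligand genes. The list had 21 tested members at 48 h, of which 14 fell, 0 rose and 7 did not pass. Adjusted over the list alone, 17 were lower and 1 higher. NODAL lies on chromosome 10 at 70432315 to 70447951 (GRCh38) and had a log2 fold change of -3.07 with a limma adjusted p of 3.9e-09. FGF8, on chromosome 10 at 101770130 to 101780369, changed by -3.77 on the log2 scale (limma adjusted p = 9.5e-08). GDF3, on chromosome 12 at 7689782 to 7695776, changed by -2.82 (limma adjusted p = 4.5e-08). FGF4, on chromosome 11 at 69771016 to 69775403, fell from 241 ± 14.8 to 22.0 ± 8.63. WNT3, on chromosome 17 at 46762506 to 46833154, fell from 176 ± 13.0 to 27.7 ± 8.57. FGF2, which E8 medium also supplies as protein, was at 1367 ± 269 and 751 ± 171, and its limma adjusted p of 0.0026 became 0.11 without 48 h replicate 1; it shares bases with NUDT6 and the strand setting of the read counting is not given. The list's median log2 fold change was -0.87, with a camera adjusted p of 1.5e-15 and adjusted p = 0.072 with an estimated correlation.

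**Figure D1:**
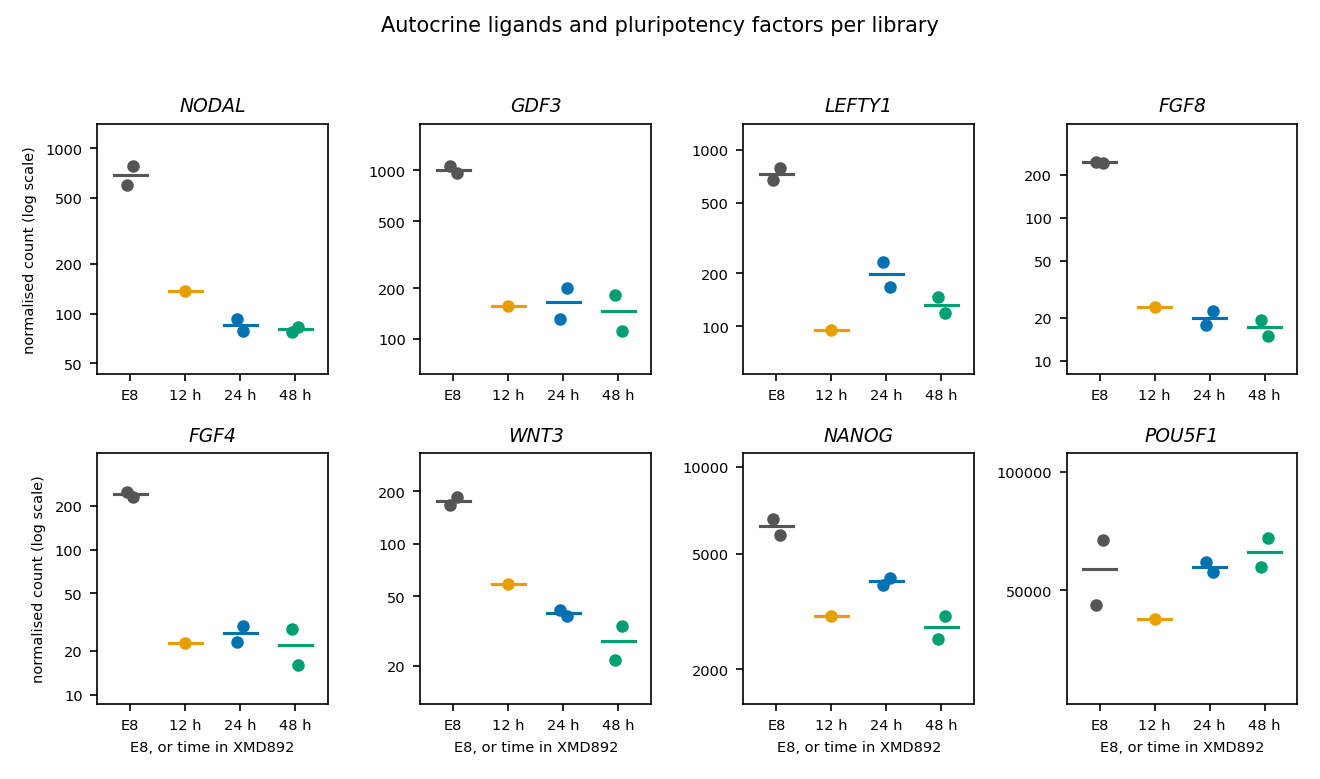
Normalised read counts (log axis) of 8 genes in each of the 7 libraries, with bars at the group means. NODAL, GDF3, LEFTY1, FGF8, FGF4 and WNT3 lay lower in every XMD892 library than in both E8 libraries, while POU5F1 at 24 h and 48 h overlapped E8.

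Of 13 tested NODAL and TGFβ target genes, 4 of which also stand in the ligand list, 10 were lower, 0 were higher and 3 did not pass. Adjusted over the list alone 11 were lower. Of the 9 not shared, with a median of -0.89, 6 were lower. LEFTY1, a secreted NODAL antagonist, fell from 729 ± 83.3 to 132 ± 20.4, a log2 fold change of -2.46. The list had a median of -1.16, a camera adjusted p of 1.5e-14 and adjusted p = 0.072 with an estimated correlation. Of 8 tested mesendoderm and primitive streak genes, 5 fell, 0 rose and 3 did not pass, and adjusted over the list alone 5 were lower. This list shares 3 genes with the ligands, and of the 5 others, with a median of -0.49, 2 were lower. MIXL1, a homeobox gene of the primitive streak, fell from 255 ± 11.7 to 61.3 ± 5.82. That list had a median of -2.03 (camera adjusted p = 1.8e-06, adjusted p = 0.14 with an estimated correlation). LEFTY1 and LEFTY2 are close paralogs, and how reads shared between them were counted is not given.

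In the core pluripotency list, 6 of 18 tested members fell, 0 rose and 12 did not pass, and adjusted over the list alone 7 were lower. NANOG, on chromosome 12 at 7787794 to 7799141, fell from 6224 ± 575 to 2799 ± 349, 2.23-fold lower, with a limma adjusted p of 1.6e-05. LIN28B, which blocks let-7 maturation, fell from 4191 ± 752 to 2154 ± 146, and TDGF1, a NODAL co-receptor, from 11066 ± 1149 to 6416 ± 287. POU5F1 stood at 56520 ± 14869 and 62563 ± 7516 and SOX2 at 5819 ± 1131 and 5711 ± 121; their log2 fold changes of 0.17 and -0.01 did not pass limma. The list's median was -0.23 (camera adjusted p = 0.00044, adjusted p = 0.22 with an estimated correlation). Of 8 tested naive state genes, 4 fell, 0 rose and 4 did not pass, and adjusted over the list alone 6 were lower. KLF4, a pluripotency factor, fell from 133 ± 0.227 to 56.6 ± 8.29, and NLRP7 from 96.1 ± 12.5 to 25.4 ± 0.794. The naive list had a median of -0.91 (camera adjusted p = 0.00042, adjusted p = 0.28 with an estimated correlation). In the neuroectoderm list SIX3 fell from 723 ± 7.26 to 324 ± 24.4 and NCAM1 rose from 204 ± 10.1 to 484 ± 73.7.

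FGF/ERK feedback targets had 5 lower, 2 higher and 10 not passing of 17 tested members, and 9 lower and 2 higher adjusted over the list alone. SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell from 1457 ± 83.8 to 679 ± 27.2, whereas EGR1, an immediate early gene, rose from 46.2 ± 1.20 to 131 ± 7.50. The median was -0.38 (camera adjusted p = 0.002, adjusted p = 0.22 with an estimated correlation). The list of ERK5, MEF2 and KLF targets also holds MAPK7, MAP2K5, MEF2A, MEF2C and MEF2D, which are parts of the pathway, and its member KLF2 was not tested. Of the list's 13 tested members 3 fell, 0 rose and 10 did not pass, with 3 lower adjusted over the list alone. The list had a median of -0.24, a camera adjusted p of 0.033 and adjusted p = 0.32 with an estimated correlation. Its camera adjusted p was 0.1 with a filter at a mean of 50, 0.15 without E8 replicate 2, 0.057 and 0.058 without 24 h replicates 1 and 2, and 0.074 without 48 h replicate 1. CDKN1A, a cyclin-dependent kinase inhibitor and p53 target, fell from 170 ± 27.0 to 60.9 ± 3.65, and 6 of 16 tested p53 targets fell, 0 rose and 10 did not pass. Adjusted over the list alone 7 p53 targets were lower and 1 higher, the median was -0.26, the camera adjusted p was 0.029 and adjusted p = 0.32 with an estimated correlation. The p53 list did not pass without E8 replicate 2 (camera adjusted p = 0.29, and 0.084 with the GC trend also removed) or with a filter at a mean of 50 (0.084). CCND1, a cyclin of G1, stood at 8977 ± 264 and 7600 ± 456 and did not pass limma (adjusted p = 0.28).

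Replication histone transcripts, which mostly end without a poly(A) tail, had 4 of 10 tested members higher, 0 lower and 6 not passing at 48 h, and 6 higher adjusted over the list alone. HIST1H2BD rose from 33.9 ± 4.68 to 126 ± 5.37 and HIST1H4H from 75.1 ± 0.0748 to 212 ± 26.0. Their median was 1.01 (camera adjusted p = 1.9e-06, adjusted p = 0.32 with an estimated correlation). The 4 other tested RNAs without a poly(A) tail, RN7SL2, RN7SL3, RMRP and SNORA73B, chosen after the histone values were seen, had a median of 0.84, which turned to -0.68 without E8 replicate 1. Genes reported to respond to bromodomain inhibition had 3 higher, 1 lower and 8 not passing of 12 tested members, and 6 higher and 2 lower adjusted over the list alone. HEXIM1, which sequesters the elongation factor P-TEFb, rose from 638 ± 143 to 1360 ± 83.4, a log2 fold change of 1.11 with a limma adjusted p of 0.00011. This list, which shares HIST1H2BD, HIST1H1C and HIST2H2BE with the histone list, had a median of 0.49 (camera adjusted p = 0.0046, adjusted p = 0.32 with an estimated correlation). Histone genes are close paralogs, and the handling of shared reads is not given.

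Metallothioneins, which bind zinc and copper, had 5 of 7 tested members lower, 0 higher and 2 not passing, with 5 lower adjusted over the list alone. MT1G fell from 720 ± 123 to 226 ± 67.7 and MT1E from 340 ± 25.3 to 176 ± 1.10, and the list's median was -0.94 (camera adjusted p = 1.9e-06, adjusted p = 0.14 with an estimated correlation); these genes are paralogs too. ATF4 target genes had 3 lower, 1 higher and 15 not passing of 19 tested members, and 6 lower and 1 higher adjusted over the list alone. SLC7A11, the cystine transporter, fell from 385 ± 76.8 to 60.8 ± 8.04, and DDIT4, an inhibitor of mTORC1, rose from 411 ± 39.2 to 878 ± 125. The ATF4 list had a median of -0.27 (camera adjusted p = 0.0066, adjusted p = 0.64 with an estimated correlation) and a camera adjusted p of 0.053 without E8 replicate 2.

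Glycolysis genes had 6 higher, 1 lower and 13 not passing of 20 tested members, and 8 higher and 1 lower adjusted over the list alone. SLC2A1, a glucose transporter, rose from 4388 ± 324 to 7871 ± 1111. The list's median was 0.23 (camera adjusted p = 0.0054, adjusted p = 0.7 with an estimated correlation), and its camera adjusted p was 0.23 without 48 h replicate 1. Of 20 tested cytosolic ribosomal protein genes 2 rose, 0 fell and 18 did not pass, with 3 higher adjusted over the list alone, a median of 0.24, a camera adjusted p of 0.0033 and adjusted p = 0.64 with an estimated correlation. Without E8 replicate 1 the camera adjusted p was 0.16, and 0.18 with the GC trend also removed. Of 19 tested nuclear genes of oxidative phosphorylation 3 rose, 0 fell and 16 did not pass, with 3 higher adjusted over the list alone, a median of 0.18, a camera adjusted p of 0.033 and adjusted p = 0.7 with an estimated correlation. The camera adjusted p was 0.23 without E8 replicate 1 (0.27 with the GC trend also removed), 0.2 without 48 h replicate 1 and 0.084 with a filter at a mean of 50.

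Trophoblast and amnion markers had 3 lower, 1 higher and 2 not passing of 6 tested members, and 5 lower and 1 higher adjusted over the list alone. ANXA3 fell from 309 ± 12.0 to 98.1 ± 30.8 and IGFBP3, which binds insulin-like growth factors, rose to 201 ± 9.92, 1.99-fold higher than in E8. The median was -0.78 (camera adjusted p = 0.0074, adjusted p = 0.28 with an estimated correlation). Without E8 replicate 2 its camera adjusted p was 0.072, and with a filter at a mean of 50 it was 0.089. Mesoderm and cardiac markers had 1 of 6 lower, 0 higher and 5 not passing, and 2 lower adjusted over the list alone. The lower gene was KDR, a VEGF receptor, which fell from 2635 ± 153 to 1109 ± 211; the median was -0.73 (camera adjusted p = 0.014, adjusted p = 0.32 with an estimated correlation). YAP and TEAD targets had 3 of 11 lower, 0 higher and 8 not passing, and 4 lower adjusted over the list alone. Their median was -0.06 (camera adjusted p = 0.033, adjusted p = 0.32 with an estimated correlation), and the camera adjusted p was 0.13 without E8 replicate 2, 0.065 without 48 h replicate 2 and 0.15 with a filter at a mean of 50.

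Of 43 lists tested at 48 h, 18 passed camera with its preset correlation, 5 up and 13 down, while 0 passed camera with an estimated correlation, 7 had an unadjusted p under 0.05 there, and 14 passed fry, which asks whether a list's genes move on balance one way. Outside the lists, the largest falls by the rule for named genes included SCNN1B, a subunit of the epithelial sodium channel, which ended at 5.18 ± 0.311, 29.1-fold lower than in E8; its log2 fold change of -4.86 was -4.17 with a pseudocount of 5. EBF2, a transcription factor, fell from 294 ± 45.7 to 9.37 ± 2.03, NTS, the neurotensin precursor, from 1107 ± 181 to 80.6 ± 19.3, and CYP2B6, a cytochrome P450, from 333 ± 9.95 to 20.7 ± 1.25. HAPLN1, a linker of hyaluronan and proteoglycans, changed by -3.83 on the log2 scale, by -4.46 without 48 h replicate 1 and by -3.21 without replicate 2. Among the largest rises, NUDT8, the neighbour of TBX10 on chromosome 11, rose from 87.9 ± 19.4 to 288 ± 7.06, and ATP6V0C, a subunit of the vacuolar proton pump, from 58.2 ± 18.1 to 218 ± 32.2. ST3GAL3, a sialyltransferase gene that overlaps KDM4A-AS1, rose from 51.7 ± 5.19 to 191 ± 0.196. PSENEN, a subunit of gamma-secretase, had a log2 fold change of 1.77. It was 0.63, and not called, without E8 replicate 1, and 2.90 without E8 replicate 2. With all libraries PSENEN did not pass DESeq2 (log2 fold change 1.36, DESeq2 adjusted p = 0.36) or limma with robust variance moderation (limma adjusted p = 0.32).

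After 24 h of XMD892, 14 of the 21 ligand genes were lower than in E8 by limma, in a comparison that spans a difference in harvest time, since E8 was sampled only at 48 h. NODAL stood at 85.6 ± 9.98 (SD, n = 2), 7.94-fold lower than in E8, FGF4 at 26.4 ± 4.96, 8.89-fold lower, and LEFTY1 at 199 ± 45.7. TBX10 reached 980 ± 163, a log2 fold change of 4.39 against E8, and VGF, a secreted neuropeptide precursor, rose from 348 ± 24.8 in E8 to 2397 ± 222. TAGLN, an actin-binding protein, rose from 547 ± 104 to 2108 ± 170, and overlaps PCSK7 on the opposite strand. DHRS2, a short-chain dehydrogenase, rose from 17.3 ± 4.73 to 114 ± 24.8.

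In limma 2652 genes passed at 24 h, 1416 higher and 1236 lower. The count was 1697 without E8 replicate 1, 4903 without E8 replicate 2, 1110 without 24 h replicate 1 and 1748 without 24 h replicate 2. Fewer genes were higher than lower without E8 replicate 1, at 781 and 916, and without 24 h replicate 1, at 528 and 582, and 24 h replicate 2, at 861 and 887. With the GC trend removed 3272 genes passed, 1475 higher and 1797 lower, and 83.3% of the 2652 kept their call and direction. The balance also turned with edgeR, to 1286 and 1326, and with DESeq2, to 1076 and 1084, so it depended on the processing.

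Of the 21 autocrine ligand genes 14 fell at 24 h, 0 rose and 7 did not pass, with 16 lower and 1 higher adjusted over the list alone, a median of -0.85, a camera adjusted p of 4.3e-12 and adjusted p = 0.17 with an estimated correlation. NODAL and TGFβ targets had 8 of 13 lower, 1 higher and 4 not passing, with 9 lower and 1 higher adjusted over the list alone (median -0.63, camera adjusted p = 5.1e-07, adjusted p = 0.22 with an estimated correlation). Mesendoderm genes had 5 of 8 lower, 0 higher and 3 not passing, with 5 lower adjusted over the list alone (median -1.88, camera adjusted p = 5.1e-05, adjusted p = 0.26 with an estimated correlation). The 5 genes outside the ligand list had a median of -0.55, 2 of them lower, and the 9 such NODAL and TGFβ targets a median of -0.37, with 4 lower and 1 higher. Core pluripotency genes had 5 of 18 lower, 2 higher and 11 not passing, with 5 lower and 2 higher adjusted over the list alone. That list did not pass camera (median -0.11, camera adjusted p = 0.12, adjusted p = 0.53 with an estimated correlation). NANOG stood at 4021 ± 165, a log2 fold change of -0.63 whose limma adjusted p of 0.0057 was 0.08 without 24 h replicate 1. Naive state genes had 3 of 8 lower, 0 higher and 5 not passing, with 3 lower adjusted over the list alone (median -0.56, camera adjusted p = 0.0055, adjusted p = 0.46 with an estimated correlation), and a camera adjusted p of 0.094 without E8 replicate 2.

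Histone transcripts had 6 of 10 higher at 24 h, 0 lower and 4 not passing, with 7 higher adjusted over the list alone. HIST1H4H stood at 392 ± 94.3, 5.08-fold above E8, and HIST1H2BD at 157 ± 4.11, and the median was 1.21 (camera adjusted p = 5.1e-07, adjusted p = 0.46 with an estimated correlation). The 4 other RNAs without a poly(A) tail had a median of 1.85 at 24 h, and of 0.13 without E8 replicate 1. Bromodomain response genes had 6 of 12 higher, 0 lower and 6 not passing, with 8 higher adjusted over the list alone. HEXIM1 stood at 1438 ± 92.3 and MYCN, a MYC-family gene, at 3492 ± 167 against 2029 ± 255 in E8; the median was 0.55 (camera adjusted p = 7.9e-05, adjusted p = 0.44 with an estimated correlation). MYC and ribosome biogenesis genes had 6 of 20 higher, 0 lower and 14 not passing, with 8 higher adjusted over the list alone. ODC1, the first enzyme of polyamine synthesis, rose from 2823 ± 92.4 to 7278 ± 1064, and the median was 0.27 (camera adjusted p = 0.0014, adjusted p = 0.33 with an estimated correlation). MYC itself changed by 0.53 on the log2 scale with a limma adjusted p of 0.016, and without 24 h replicate 1 the limma adjusted p was 0.3.

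Cholesterol synthesis genes had 7 of 22 higher at 24 h, 0 lower and 15 not passing, with 8 higher adjusted over the list alone. MVD, an enzyme of the mevalonate pathway, rose from 1778 ± 592 to 4251 ± 1256, and LSS, lanosterol synthase, from 4502 ± 1157 to 7895 ± 680. The median was 0.3 (camera adjusted p = 2e-04, adjusted p = 0.7 with an estimated correlation), and the camera adjusted p was 0.06 without 24 h replicate 1. G2/M genes had 5 of 20 lower, 0 higher and 15 not passing, with 6 lower adjusted over the list alone. CENPF, a kinetochore protein, was at 6492 ± 1015 in E8 and 4407 ± 127 at 24 h (limma adjusted p = 0.014, but 0.08 and 0.1 without 24 h replicates 1 and 2). The G2/M median was -0.33 (camera adjusted p = 3e-04, adjusted p = 0.53 with an estimated correlation).

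Hypoxia response genes had 5 of 14 lower at 24 h, 2 higher and 7 not passing, with 6 lower and 2 higher adjusted over the list alone. DDIT4 fell from 411 ± 39.2 to 136 ± 21.5 and PDK1, which inhibits pyruvate dehydrogenase, from 891 ± 172 to 403 ± 8.97, whereas ADM, the adrenomedullin precursor, rose from 366 ± 72.2 to 788 ± 232. The median was -0.36 (camera adjusted p = 0.035, adjusted p = 0.46 with an estimated correlation), and the camera adjusted p was 0.094 without E8 replicate 2 and 0.12 without 24 h replicate 2. ATF4 targets had 4 of 19 lower, 2 higher and 13 not passing, with 5 lower and 2 higher adjusted over the list alone (median -0.26, camera adjusted p = 0.026, adjusted p = 0.7 with an estimated correlation), and a camera adjusted p of 0.14 without E8 replicate 2 and 0.2 without 24 h replicate 2. Mesoderm and cardiac markers had 1 of 6 lower, 0 higher and 5 not passing, with 1 lower adjusted over the list alone (median -0.9, camera adjusted p = 0.035, adjusted p = 0.48 with an estimated correlation). The lower gene was KDR, at 1086 ± 51.4, and the camera adjusted p of that list was 0.089 without E8 replicate 2, 0.05 without 24 h replicate 1, 0.055 with quantile normalisation and 0.066 with the GC trend removed and E8 replicate 1 left out. Trophoblast and amnion markers had 4 of 6 lower, 1 higher and 1 not passing, with 4 lower and 1 higher adjusted over the list alone (median -0.93, camera adjusted p = 0.047, adjusted p = 0.46 with an estimated correlation). GABRP, a GABA receptor subunit, fell from 166 ± 16.7 to 62.7 ± 2.66. The trophoblast list had a camera adjusted p of 0.2 without E8 replicate 2, 0.12 with the GC trend removed (0.066 and 0.21 also without E8 replicates 1 and 2), 0.39 with a filter at a mean of 50, 0.051 with rescaling to the same total and 0.055 with quantile normalisation. Of 43 lists 13 passed camera at 24 h, 4 up and 9 down; 0 passed with an estimated correlation, 4 had an unadjusted p under 0.05 there, and 11 passed fry.

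The calls at 24 h and 48 h shared 1143 genes in the same direction, 517 higher and 626 lower, and 8 in opposite directions; independent lists of these sizes would share 71.9 higher and 79.7 lower. In 100 simulations of unchanged groups with shared E8 libraries the mean overlap was 0.07 genes and the highest 1. Groups without changed genes give few calls, so this overlap was low by design. The simulations also drew genes independently and left out the difference between the E8 libraries along GC content. They therefore cannot show how many shared calls that difference makes. The log2 fold changes at both times correlated at 0.762 across genes, against 0.483 in the simulations, where the shared E8 libraries alone make a correlation. Their covariance was 0.247, against 0.038 in the simulations, a difference of 0.209. With 2 E8 libraries the controls were not split, and part of the excess in shared calls may come from them. The overlap was 3036 without E8 replicate 2, 713 without 24 h replicate 1, 525 without 48 h replicate 1, 546 without 48 h replicate 2 and 1796 with the GC trend removed. Without E8 replicate 2 the overlap held 1918 higher and 1118 lower genes (1008 and 923 with the GC trend also removed), and without 48 h replicate 1 it held 157 and 368.

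In the single library at 12 h of XMD892, 9 of the 21 ligand genes were lower by limma, again against E8 at 48 h. NODAL stood at 137, 4.95-fold lower than in E8, FGF8 at 23.6, 9.98-fold lower, GDF3 at 156 and LEFTY1 at 95.5. TBX10 stood at 1656, 35.7-fold higher than in E8, VGF at 4155 and TAGLN at 4847. ANXA1, a phospholipid-binding protein, was at 312 against 11.1 ± 1.63 in E8 (SD, n = 2), and SULF1, a heparan sulfatase, at 38.6 against 473 ± 20.2. The tests at this time rest on the spread within the other groups.

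At 12 h 1219 genes passed limma, 419 higher and 800 lower. The count was 1874 without E8 replicate 1, 2931 without E8 replicate 2 and 2541 with the GC trend removed, which kept 98.8% of the 1219 in the same direction. The balance turned without E8 replicate 2, to 1672 higher and 1259 lower, while without E8 replicate 1 it was 691 and 1183.

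Of the 21 ligand genes 9 were lower at 12 h, 0 higher and 12 did not pass, with 15 lower and 1 higher adjusted over the list alone (median -0.74, camera adjusted p = 8.4e-11, adjusted p = 0.14 with an estimated correlation). NODAL and TGFβ targets had 7 of 13 lower, 1 higher and 5 not passing, with 10 lower and 1 higher adjusted over the list alone (median -0.73, camera adjusted p = 1.5e-09, adjusted p = 0.14 with an estimated correlation). Mesendoderm genes had 4 of 8 lower, 0 higher and 4 not passing, with 6 lower adjusted over the list alone (median -1.59, camera adjusted p = 2.2e-06, adjusted p = 0.17 with an estimated correlation), and MIXL1 stood at 33.3. Outside the ligand list, 3 of 9 NODAL and TGFβ targets were lower and 1 higher (median -0.62), and 1 of 5 mesendoderm genes was lower (median -1.4). Core pluripotency genes had 2 of 18 lower, 0 higher and 16 not passing, with 4 lower adjusted over the list alone (median -0.26, camera adjusted p = 0.036, adjusted p = 0.36 with an estimated correlation), and NANOG stood at 3059. The list did not pass camera with replicate numbers as a block (adjusted p = 0.092) or with the GC trend removed and E8 replicate 1 left out. Naive state genes had 1 of 8 lower, 0 higher and 7 not passing, with 4 lower adjusted over the list alone (median -0.65, camera adjusted p = 0.019, adjusted p = 0.36 with an estimated correlation). The lower gene was NLRP7, at 20.4, and the camera adjusted p was 0.064 without E8 replicate 1 (0.051 with the GC trend also removed) and 0.1 without E8 replicate 2. Mesoderm and cardiac markers had 1 of 6 lower, KDR at 1160, 0 higher and 5 not passing, with 3 lower adjusted over the list alone (median -1.16, camera adjusted p = 0.019, adjusted p = 0.36 with an estimated correlation), and a camera adjusted p of 0.064 without E8 replicate 1 (0.058 with the GC trend also removed).

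Histone transcripts had 5 of 10 higher at 12 h, 0 lower and 5 not passing, with 8 higher adjusted over the list alone (median 1.67, camera adjusted p = 1.2e-09, adjusted p = 0.35 with an estimated correlation). HIST1H4H stood at 597 and HIST1H2BD at 234, and the 4 other RNAs without a poly(A) tail had a median of 0.17, which turned to -0.73 without E8 replicate 1. Bromodomain response genes had 2 of 12 higher, 0 lower and 10 not passing, with 4 higher adjusted over the list alone (median 0.38, camera adjusted p = 0.00016, adjusted p = 0.35 with an estimated correlation). The higher genes were HIST1H2BD and HEXIM1, which stood at 1791. MYC and ribosome biogenesis genes had 5 of 20 higher, 0 lower and 15 not passing, with 6 higher adjusted over the list alone (median 0.31, camera adjusted p = 2.2e-05, adjusted p = 0.17 with an estimated correlation), and ODC1 stood at 8613. Metallothioneins had 3 of 7 higher, 0 lower and 4 not passing, with 4 higher adjusted over the list alone (median 0.73, camera adjusted p = 0.00045, adjusted p = 0.23 with an estimated correlation), and MT1G stood at 1488 and MT1E at 939. HSPA8, a constitutive chaperone, was at 65813 against 39738 ± 3129 in E8, the 1 higher gene of 11 tested heat shock genes, with 0 lower, 10 not passing and 1 higher adjusted over the list alone. The heat shock list had a median of 0.34 (camera adjusted p = 0.046, adjusted p = 0.36 with an estimated correlation). Its camera adjusted p was 0.069 with a filter at a mean of 50, 0.063 with quantile normalisation and 0.091 with replicate numbers as a block. It also did not pass without E8 replicate 1, with the GC trend left in or removed. Leaving out any 1 of the 24 h or 48 h replicates lost its call too.

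Hypoxia response genes had 3 of 14 lower at 12 h, 1 higher and 10 not passing, with 5 lower and 2 higher adjusted over the list alone (median -0.43, camera adjusted p = 0.03, adjusted p = 0.36 with an estimated correlation), and DDIT4 stood at 96.6 and BNIP3, a mitophagy receptor, at 1157 against 2510 ± 23.3 in E8. ATF4 targets had 4 of 19 lower, 1 higher and 14 not passing, with 7 lower and 2 higher adjusted over the list alone (median -0.21, camera adjusted p = 0.019, adjusted p = 0.59 with an estimated correlation), and a camera adjusted p of 0.06 without E8 replicate 2. CHAC1, which degrades glutathione, was at 67.6 against 229 ± 27.1, and SLC7A5, an amino acid transporter, at 16441 against 8383 ± 1204. Of 43 lists 13 passed camera at 12 h, 5 up and 8 down; 0 passed with an estimated correlation, 6 had an unadjusted p under 0.05 there, and 16 passed fry.

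**Figure D2:**
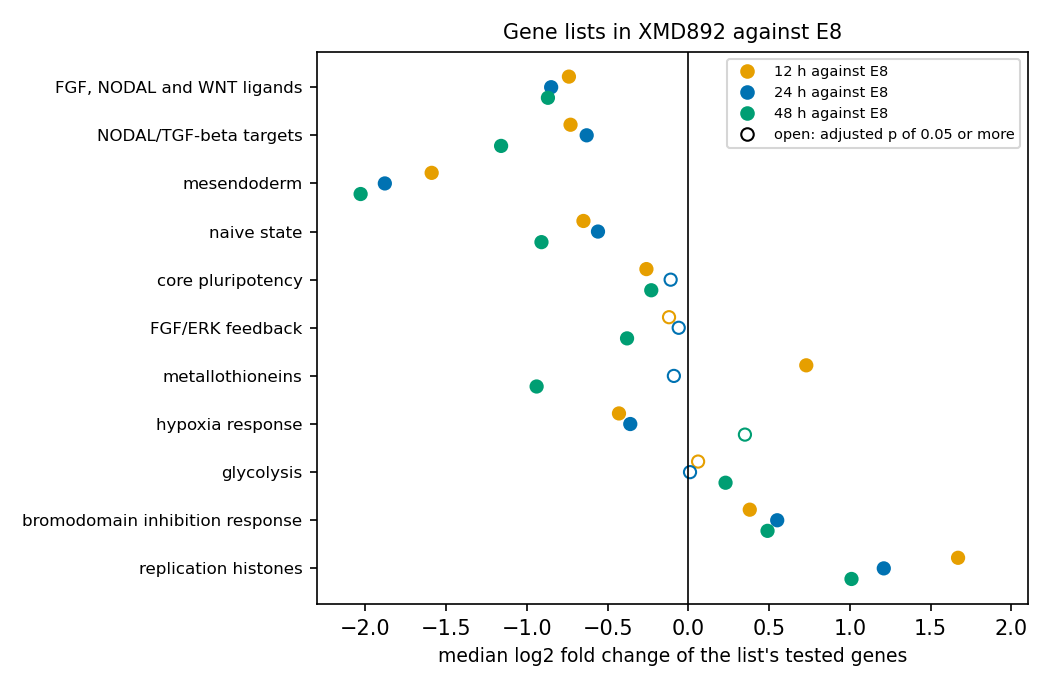
Median log2 fold change against E8 of 11 gene lists at 12, 24 and 48 h of XMD892, with open symbols where the camera adjusted p was 0.05 or more. Ligand genes had medians of -0.74, -0.85 and -0.87, and metallothioneins went from 0.73 at 12 h to -0.94 at 48 h.

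The comparison of 48 h with 24 h of XMD892 asked which genes went on changing under the inhibitor, with harvest time differing in the same way. DDIT4 rose from 136 ± 21.5 at 24 h (SD, n = 2) to 878 ± 125 at 48 h (n = 2), 6.43-fold higher, TXNIP from 240 ± 29.3 to 1462 ± 83.6 and STC1, stanniocalcin, from 163 ± 2.59 to 873 ± 67.9. SLC16A3, a lactate exporter that overlaps CSNK1D, rose from 254 ± 7.87 to 948 ± 95.8. TAGLN fell from 2108 ± 170 to 364 ± 21.9, 5.78-fold lower, VGF from 2397 ± 222 to 586 ± 142, and MT1H from 111 ± 31.4 to 22.8 ± 1.37. NODAL and MIXL1 had log2 fold changes of -0.08 and -0.15 between the times, with limma adjusted p of 0.92 and 0.86.

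Between the times 197 genes passed limma, 57 higher at 48 h and 140 lower, which is 28.9% higher. The count was 1046 without E8 replicate 1, 1016 without E8 replicate 2, 107 without 24 h replicate 1, 57 without 48 h replicate 1, 117 without 48 h replicate 2 and 1043 from a fit of these groups alone. With the GC trend removed 430 genes passed, of which 39.8% were higher, and 93.4% of the 197 kept their call.

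The gene lists were tested between these times only after the data had been seen. Hypoxia response genes had 4 of 14 higher, 1 lower and 9 not passing, with 8 higher and 1 lower adjusted over the list alone (median 0.56, camera adjusted p = 6.4e-09, adjusted p = 0.15 with an estimated correlation). BNIP3 rose from 1361 ± 83.8 to 3065 ± 323. Glycolysis genes had 2 of 20 higher, 0 lower and 18 not passing, with 7 higher adjusted over the list alone (median 0.18, camera adjusted p = 5e-05, adjusted p = 0.53 with an estimated correlation). Metallothioneins had 4 of 7 lower, 0 higher and 3 not passing, with 5 lower adjusted over the list alone (median -1.3, camera adjusted p = 7.5e-11, adjusted p = 0.15 with an estimated correlation), and MT1G fell from 671 ± 53.7 to 226 ± 67.7. FGF/ERK feedback targets had 4 of 17 lower, 0 higher and 13 not passing, with 7 lower and 1 higher adjusted over the list alone (median -0.31, camera adjusted p = 1.8e-05, adjusted p = 0.15 with an estimated correlation). DUSP5, a phosphatase of ERK, changed by -0.94 on the log2 scale (limma adjusted p = 0.002, but 0.13 without 24 h replicate 1 and 0.075 without 48 h replicate 1). MYC and ribosome biogenesis genes had 2 of 20 lower, 0 higher and 18 not passing, with 4 lower adjusted over the list alone (median -0.2, camera adjusted p = 1.8e-05, adjusted p = 0.15 with an estimated correlation). In the p53 list 2 of 16 were lower, 0 higher and 14 did not pass, with 2 lower adjusted over the list alone (median -0.35, camera adjusted p = 0.0018, adjusted p = 0.32 with an estimated correlation), and CDKN1A fell from 162 ± 17.0 to 60.9 ± 3.65. Of the 43 lists 20 passed camera between the times, 5 up and 15 down; 0 passed with an estimated correlation, 6 had an unadjusted p under 0.05 there, and 6 passed fry.

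**Figure D3:**
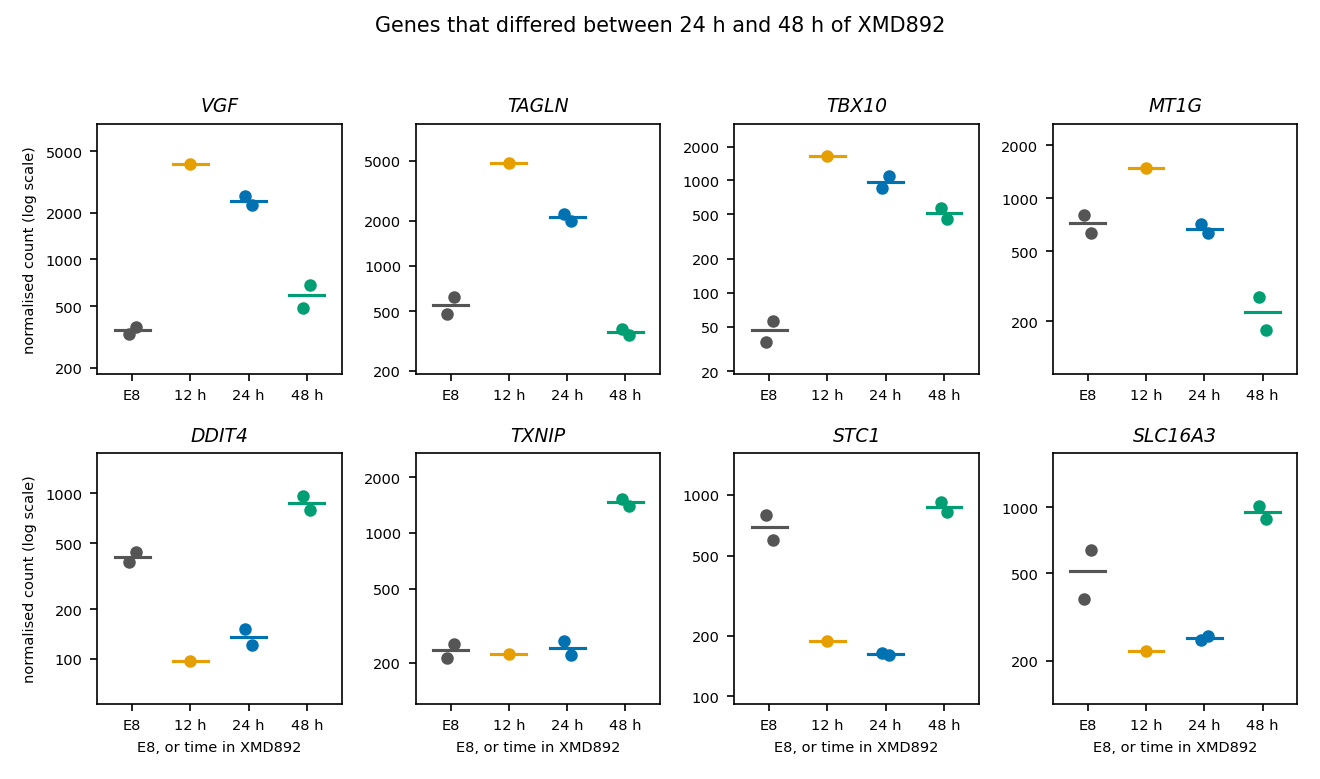
Normalised read counts (log axis) of 8 genes in each library by harvest time, with E8 at 48 h shown for reference. VGF and TAGLN stood highest at 12 h, at 4155 and 4847, and TXNIP and DDIT4 highest at 48 h, at means of 1462 and 878.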

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

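The tests on non-polyadenylated RNA, S phase and harvest time, and all settings with the GC trend removed, were chosen only after the result was seen.

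Between 24 h and 48 h of XMD892, 197 genes differed by limma at a Benjamini-Hochberg adjusted p under 0.05. The E8 group, sampled only at 48 h, cancels from this difference, which therefore includes harvest time. The difference in log2 fold change (48 h minus 24 h) was 2.69 for DDIT4, 2.61 for TXNIP, 2.41 for STC1, 1.92 for MIR210HG and 1.89 for SLC16A3. It was -2.53 for TAGLN, -2.21 for MT1H, -2.05 for VGF, -1.89 for GCNT4, -1.67 for SPP1, -1.39 for CDKN1A, -1.26 for NTS, -1.07 for D21S2088E, -0.98 for NUDT8 and -0.94 for TBX10. It was -0.87 for HIST1H4H, -0.86 for HIST1H2AC, -0.67 for SPRY4 and -0.59 for MYC. Without 48 h replicate 1 the limma adjusted p of NTS was 0.075. Without 24 h replicate 2, 48 h replicate 1 and 48 h replicate 2 in turn, it was 0.15, 0.087 and 0.23 for TBX10, 0.23, 0.17 and 0.11 for NUDT8, 0.43, 0.49 and 0.088 for HIST1H4H and 0.53, 0.44 and 0.16 for HIST1H2AC. Without 24 h replicates 1 and 2 and 48 h replicate 2 it was 0.088, 0.075 and 0.28 for D21S2088E. Without 24 h replicates 1 and 2 and 48 h replicates 1 and 2 it was 0.2, 0.081, 0.12 and 0.17 for SPRY4 and 0.63, 0.085, 0.37 and 0.24 for MYC.

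Genes that were higher at 48 h than at 24 h numbered 57, of which 15 were also higher than E8 at 48 h, in comparisons that share the 48 h libraries. When each comparison was given a different 48 h library, 7 of 26 genes were higher than E8 by limma and 2 lower (median log2 change 0.21), and the other way 5 of 10 were higher and 0 lower (median 0.73), adjusted over those genes. TXNIP, DDIT4, MIR210HG and SLC16A3 were among the genes that passed both ways, though SLC16A3 was not called over all genes without 48 h replicate 1. These genes stood above E8 at the same harvest time, so time in culture alone does not set their level at 48 h. The test cannot show that the effect of XMD892 grew between 24 h and 48 h, because E8 was not sampled at 24 h. The 42 genes of the 57 that were not higher than E8 had a median log2 change of 0.19 against E8 at 48 h and 1 against 24 h. Of these 42, 32 were lower than E8 at 24 h. For them an effect of harvest time and a transient effect of XMD892 cannot be told apart, because E8 was sampled only at 48 h. A GC trend between libraries is not the whole cause, since 55 of the 57 kept their call with the trend removed. A further effect of the inhibitor between the times may account for the genes that passed both ways. That hypothesis was found on the same data, and the comparison with E8 at 48 h cannot decide it.

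At 12, 24 and 48 h, 5, 6 and 4 of 10 histone transcripts were higher, as was HEXIM1, and the histone list had camera adjusted p of 0.35, 0.46 and 0.32 with an estimated correlation. The GC trend of E8 replicate 1 is not the whole cause: with the trend removed the histone median at 48 h was 0.95 instead of 1.01, and HEXIM1's log2 change was 1.08 instead of 1.11. At 48 h a larger share of cells in S phase is argued against by the G1/S and replication list, whose median was 0.08 with an SD of 0.24. Its median was 0.14 at 24 h and 0.08 at 12 h. At 24 h, however, 3 of its 20 members were higher and 0 lower, and 5 of 20 G2/M genes were lower and 0 higher. A change in the share of cells in S phase at 24 h therefore stays open. RNA without a poly(A) tail carried into some libraries stays open: RN7SL2, RN7SL3, RMRP and SNORA73B, the 4 such RNAs measured, had a median of 0.84 at 48 h, 1.85 at 24 h and 0.17 at 12 h, and in a second test chosen later, without E8 replicate 1, -0.68, 0.13 and -0.73 against histone medians of 1.21, 1.14 and 1.55. A response to loss of bromodomain or kinase function may also raise these genes, but with 1 compound and no separate inhibitor of either this was not tested.

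The number of genes called at 48 h rose from 1884 to 4038 without E8 replicate 2. With the GC trend removed 3078 genes passed with all libraries. Leaving out E8 replicate 2 kept the count within 1.5 times that, as predicted if the GC trend of E8 replicate 1 made the rise. But the count with all libraries had itself risen, and with the trend removed the counts without 1 or the other E8 library still differed. The test therefore cannot tell how much of the rise the GC trend made. Without E8 replicate 1 the counts were 1658 with the trend removed and 1600 with the trend left in. No biological explanation was tested for a difference between replicates of the same group.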

How the results depend on the processing

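Of the tests in this part, those with the GC trend removed were chosen only after the result was seen, and the others before the data were examined. No named gene or list with a call reversed its direction under these settings, which were not run for the lists between 24 h and 48 h. Called genes that are not named were not checked for this. In the numbers below, the GC trend removed without E8 library 1 or 2 stands among the settings other than leaving out 1 library. Of the values for named genes under settings other than leaving out 1 library, 5609 kept their side of the threshold, 193 lost their call and 14 gained one; leaving out 1 library gave 2034, 332 and 7. For gene lists these numbers were 1554, 78 and 33, and 724, 31 and 19. Of the counts, 98 stayed within 1.5 times the reported count and 15 did not, and 30 and 18 when 1 library was left out. A fit of only the groups compared gave 1043 genes between 24 h and 48 h, where the reported count was 197. Both fits give the same log2 fold changes, so the counts differ through the estimate of spread. The reported fit includes the E8 pair in that estimate, and the other does not. The SD of the log2 difference between replicates was 0.466 in E8, 0.395 at 24 h and 0.412 at 48 h. With the GC trend removed the counts were 3078 at 48 h, 2541 at 12 h, 430 between 24 h and 48 h and 1796 shared by 24 h and 48 h. Also without E8 library 1 they were 1850 at 12 h and 679 between the times, and without E8 library 2 they were 3011 at 48 h, 2567 at 12 h, 701 between the times and 1931 shared. Leaving out 1 library gave 751 to 4038 genes at 48 h, 1110 to 4903 at 24 h, 996 to 2931 at 12 h, 57 to 1046 between the times and 525 to 3036 shared. A filter at a mean of 50 left 10 lists passing camera at 48 h, with fewer members tested. Camera with an estimated correlation passed 0 lists at 48 h, 24 h and 12 h, with 7, 4 and 6 at an unadjusted p under 0.05 and 14, 11 and 16 passing fry. The rise at 48 h without E8 replicate 2 was tested against the GC trend. For the other changes, apart from the filter and the fit of only the groups compared, the cause was not tested. Replicate numbers as a block gave 1955, 2630 and 1231 genes at 48, 24 and 12 h, 290 between the times and 1202 shared, and correlations between replicate numbers across groups of -0.035, -0.048 and -0.071 showed no pairing. Depth limited genes with few reads: 3 reads correspond to a normalised count between 2.48 and 3.24.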

Other observations

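The tests of lists between 24 h and 48 h, the choice of APELA and the strict bound of the test on neighbouring genes were made only after the result was seen.

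Of 7 tested fibroblast and stromal markers, 2 fell between 24 h and 48 h, 0 rose and 5 did not pass limma, with 2 lower adjusted over the list alone. Their median log2 fold change was -0.08 and their mean -0.63 (camera adjusted p = 0.0018, adjusted p = 0.35 with an estimated correlation). COL1A1, a chain of collagen, was at 1534 at 12 h, 867 ± 21.8 at 24 h (SD, n = 2) and 342 ± 25.7 at 48 h, against 535 ± 76.4 in E8. Markers of the BMP and ID group had 1 higher, 3 lower and 5 not passing of 9 between the times (2 higher and 5 lower adjusted over the list alone), with a median of -0.54, a camera adjusted p of 0.015 and adjusted p = 0.41 with an estimated correlation. ID3, an inhibitor of differentiation, was at 1495 ± 379 in E8 and 4030 ± 423 at 24 h. APELA, a peptide hormone of early embryos, fell from 428 ± 132 in E8 to 174 ± 39.8 at 24 h and was at 562 ± 23.9 at 48 h.

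TBX10 and NUDT8, neighbours on chromosome 11, were both higher at 12, 24 and 48 h. The hypothesis that genes higher at 48 h lie next to each other more often than by chance was tested on adjacent pairs of tested genes. There were 53 such pairs with both genes higher, 51 of them without histone pairs, against a mean of 40.7 and a highest value of 64 in 10000 random reassignments of the calls. The count lay exactly on the upper bound set for chance, 53, and 3.02% of the reassignments were as high, so the test leaves open whether neighbours may rise together.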
